A study of Homo sapiens with 12 samples.

How the data were processed

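Total RNA of CHRF288-11 cells was hybridized to Illumina human BeadChips, 12 arrays in 4 groups of 3: untreated cells and cells given Wnt3a at 150 ng/mL, Wnt5a at 1200 ng/mL or both for 8 h, after 16 h without serum. The series calls the 3 arrays of each group biological replicates. The arrays lay on 2 BeadChips of 6 arrays. Chip 1 held Untreated 2 and 3, Wnt3a 2 and 3, and Wnt5a 1 and 3. Chip 2 held Untreated 1, Wnt3a 1, Wnt5a 2 and all 3 arrays of the combination, so that the combination met each other group on chip 2 only.

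The authors deposited a signal for each of 48803 probes on each array, as an intensity that had not been normalized. The deposited detection values were a fraction between 0 and 1 that ran opposite to a p-value, with 1 for the brightest probes, so the detection p was taken as 1 minus that fraction. The steps of that fraction implied 759 negative control values per array. The authors also deposited a value table in log2 units, whose values followed the rank order of the signals within each array and had equal quantiles on all arrays; lumi is named by the authors, with no version and no role stated. That table was used only as an alternative.

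The signals were background-corrected by the normexp method with the mean and spread of the negative controls inferred from the detection p, given an offset of 16, quantile normalized and put on the log2 scale (limma 3.58.1 in R 4.3.3). Of the 48803 probes, 14051 with a detection p under 0.01 on at least 3 arrays were tested, for 11099 genes. Gene symbols came from the platform's current annotation for 11775 tested probes and only from the deposited file for 2274. Among the named genes PTH2, MAP1B, CCL4L1, CCL4L2, AGPAT4, CCDC46, ADM2, METRNL, HERPUD1, FAM89A, ZNRF3 and JTV1 rest on the file's own symbol. Where a gene was detected on 0 arrays of a group, its fold was computed against the larger, on each of these arrays, of the array's lowest detected signal and the gene's own value, and is given as a lower bound, or no fold is given. HAVCR2, CCL4L2, TRIM71, SESN2, QKI and CASS4 were detected on only 1 array of a group they were compared in, so the size of their fitted change depends on the background correction; for the last 4 no size is given in those comparisons.

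A linear model with 4 group means and a chip term was fitted to all 12 arrays with limma (lmFit, contrasts.fit, eBayes with default settings; 7 residual and 5.04 prior degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg over the tested probes of each comparison, with a threshold of 0.05. The comparisons were each treatment with untreated cells, the combination with each ligand, Wnt3a with Wnt5a, the interaction (the effect of Wnt3a on top of Wnt5a minus its effect alone), the average effect of each ligand, and a moderated F test over the 4 groups. Fold changes are log2 differences of chip-adjusted means with their standard error (SE). Folds given as lower bounds came instead from group means without chip adjustment. They have no SE and leave out sampling error. Within-chip values were the differences between groups on 1 chip: 2 arrays against 2 on chip 1 and 1 against 1 on chip 2, or 3 against 1 for the combination. The number of arrays limits the precision.

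There were 25 gene lists, with 835 entries of which 832 were on the array and 626 tested: Wnt feedback regulators, canonical Wnt target genes, canonical Wnt pathway components, non-canonical Wnt components, megakaryocyte and platelet genes, proplatelet cytoskeleton, immediate early and ERK feedback, NF-kB and inflammatory genes, interferon response, TGF-beta and BMP targets, cholesterol synthesis, unfolded protein and amino acid stress, heat shock, p53 and apoptosis, S phase and DNA replication, mitosis, ribosome biogenesis and MYC targets, ribosomal proteins, hypoxia and glycolysis, cell adhesion and integrins, erythroid genes, monocyte and granulocyte genes, lymphoid genes, stem and progenitor genes, and housekeeping genes. Each was tested with camera at a preset correlation of 0.01 between genes, 1 probe per gene (the brightest tested), with adjustment over the 25 lists of a comparison. The same test with an estimated correlation, and fry, were run beside it. The preset correlation also gave list calls in splits of the arrays that mixed the groups, given at the end. fry tests whether the genes of a list move one way on balance and does not compare them with other genes. Counts of members that passed are given over all probes and adjusted over the list alone.

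The lists, the model, the alternatives and the rule for named genes were chosen before the data were examined. In each comparison of 2 groups the rule took, among probes that passed and carried a symbol, the 10 largest rises and the 10 largest falls, 1 probe per gene (its brightest passing probe), provided that the chip-adjusted values of the 2 groups did not overlap. Chance gives such a separation in 10% of genes with 3 arrays against 3. It added up to 10 members of the lists with the smallest adjusted p. With fewer than 5 probes past the threshold in a direction, it took those and the 5 with the smallest p, stated as not passed; for the interaction and the average effects it took 5 each way. AXIN2, NKD1, LEF1, TCF7, SP5, RNF43, ZNRF3, CCND1, MYC, CTNNB1, ITGA2B, ITGB3, GP1BA, GP9, PF4, GATA1 and NFE2 were always named. Members named as examples of a list beyond this rule were chosen after their values were seen.

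Alternatives changed 1 choice at a time, except that 1 of the fits with a replicate block also left out the chip term: no background correction, median scaling, the authors' table, 3 other filters, the handling of the chip and of the replicate number, the 2 groups alone, the variance model, array weights, the threshold, adjustment over 6 comparisons together, and each array left out in turn with the normalization and the filter kept. The fit was tested on simulated data with 200 of 14051 probes changed. A change of 0.25 in log2 was recovered in 8.96% of probes for Wnt3a, 11.9% for Wnt5a and 4.48% for the combination, and one of 0.5 in 85.1%, 88.1% and 65.7%. A list shifted by -0.2 was recovered, with 1 of 25 lists called. The simulated noise was drawn separately for each probe. It therefore does not show how often lists of correlated genes would be called without a shift. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.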

Results

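Gene expression was measured in CHRF288-11, a human megakaryoblastic cell line, on 12 BeadChip arrays, 3 for each of 4 groups: untreated cells and cells given Wnt3a, Wnt5a or both ligands. Wnt3a is the usual activator of beta-catenin signalling and Wnt5a the usual non-canonical ligand. Mean signals before normalization ran from 364.4 to 378.3 on chip 1 and from 312.1 to 347.5 on chip 2, which held the whole combination. Between 12511 and 14088 of the 48803 probes were detected on an array. Correlations of the normalized values were 0.994 to 0.997 within groups and 0.989 to 0.997 between groups.

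Wnt5a at 1200 ng/mL changed more probes than Wnt3a at 150 ng/mL. Ligand and amount of added protein cannot be told apart in these counts, since each ligand was given at 1 dose and the series has no vehicle group. Of 14051 probes tested, 213 changed with Wnt3a, 737 with Wnt5a and 1092 with both, each against untreated cells. Adding Wnt5a to Wnt3a changed 648 probes, while adding Wnt3a to Wnt5a changed 17, all of them higher. The F test over the 4 groups gave 1236 probes. The chip term itself was significant for 104 probes. Sizes of change depend on the background treatment: of 149 calls of named genes, 91 had a log2 value over 1.5 times smaller in the authors' table and 55 without background correction, and 0 were larger by as much.

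**Figure D1:**
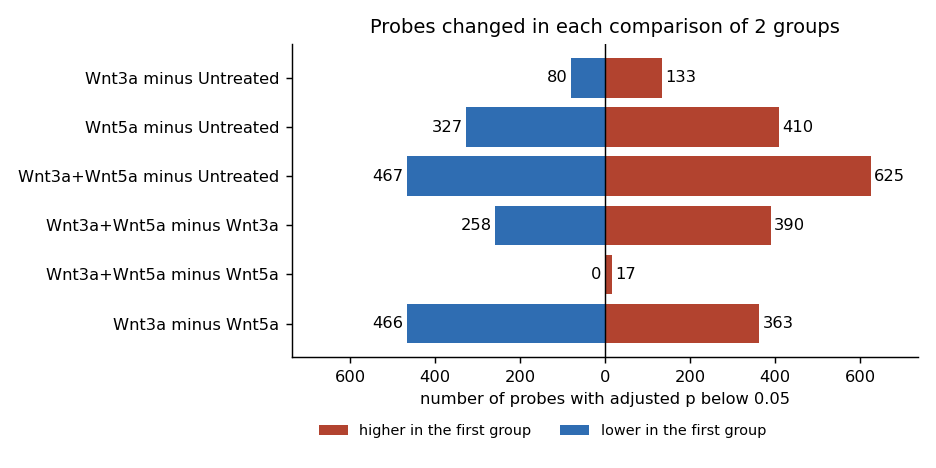
Number of probes with an adjusted p below 0.05 in each comparison of 2 groups, higher (right) and lower (left) in the first group. The bars run from 133 higher and 80 lower for Wnt3a minus Untreated to 625 higher and 467 lower for the combination minus Untreated; for the combination minus Wnt5a there were 17 higher and 0 lower.

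The first comparison asked what Wnt3a alone did. Cells given Wnt3a had more NKD1, a Dishevelled-binding inhibitor that beta-catenin signalling induces. NKD1 was detected on 0 of 3 untreated arrays and on 3 of 3 Wnt3a arrays, at least 1.27-fold higher (adjusted p = 0.00146). The hypoxia-inducible transcription factor EPAS1 rose 2.82-fold (95% CI of the log2 value 1.37 to 1.63; adjusted p = 1.05e-07), and SPRY1, an inhibitor of receptor tyrosine kinase signalling, rose by 1.11 ± 0.09 in log2 (SE, n = 3 per group; adjusted p = 3.26e-05). The complement C5a receptor C5AR1 fell by 0.84 ± 0.09 (adjusted p = 0.000417).

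Other large rises were LRRC75A (1.66), PTH2 (1.57), KCTD12 (1.46), the microtubule-associated MAP1B (1.42), MMD (1.22), DCUN1D3 (0.98), the TGF-beta docking protein LRRC32 (0.98) and the hyaluronidase CEMIP2 (0.94). Among list members MYCN rose by 0.74, MECOM by 0.69, ADM by 0.56, and the DNA damage genes RRM2B and GADD45A by 0.46 and 0.45. A second tested probe of RRM2B did not pass (0.23, adjusted p = 0.521). Large falls were those of the forkhead factor FOXA2 (-0.68), the metallothionein MT1X (-0.68), the homeobox gene IRX3 (-0.67), the zinc exporter SLC30A1 (-0.63), ISL2 (-0.63), MYEOV (-0.61), cyclin D1 (CCND1, -0.61) and the ETS factor ETV5 (-0.60). METRNL was at least 1.42-fold lower, and GATA2 (-0.46) and the chemokine gene CCL2 (-0.39) also fell. In total 133 probes were higher and 80 lower, 9 of them at least 2-fold higher and 0 at least 2-fold lower.

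By list, immediate early and ERK feedback genes were lower with Wnt3a, with a median shift of -0.18 over 33 tested genes (camera adjusted p = 6.96e-07; adjusted p = 0.127 with an estimated correlation). Of these, 3 fell (ETV5, DUSP5 and JUN), 1 rose (SPRY1) and 29 did not pass; adjusted over the list alone, 13 fell and 1 rose. Ribosome biogenesis and MYC targets shifted by -0.11 (adjusted p = 0.000212; adjusted p = 0.0465 with an estimated correlation), although 0 of 28 members passed singly and 2 fell when adjusted over the list alone. The stress list of unfolded protein and amino acid genes shifted by -0.08 (adjusted p = 0.00173; adjusted p = 0.345 with an estimated correlation), with DDIT4 the 1 member of 28 that fell (4 when adjusted over the list alone). Mitosis genes shifted by 0.05 (adjusted p = 0.0136; adjusted p = 0.107 with an estimated correlation), with 0 of 40 members past the threshold either over all probes or adjusted over the list alone. NF-kB and inflammatory genes shifted by -0.05 (adjusted p = 0.0317; adjusted p = 0.163 with an estimated correlation). Of its 20 members 4 fell (CCL2, BCL3, IL1B and TNF), as many as when adjusted over the list alone, and its median was 0.01 under median scaling.

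All 213 probes had the same sign on chip 1 and on chip 2. They were called on these same arrays, so their selection largely ensured that agreement. The same holds for the probes called in each comparison below, and the chips do not replicate each other in this respect. The medians of the 5 lists, in the order given, were -0.19, -0.10, -0.09, 0.05 and -0.01 on chip 1 and -0.15, -0.13, -0.08, 0.08 and -0.15 on chip 2. The share of called probes that were higher was 62.4% and became 82.6% of 195 under median scaling. The count was 76 and 135 without Untreated 1 or 3, 65.3% of the full count without Untreated 2, and 96, 91 and 117 without Wnt3a 1, 2 or 3; without Untreated 1 the calls of GATA2 (adjusted p = 0.0589), MT1X (0.0586) and ETV5 (0.0513) ended, as did those of CCND1 (0.165), ISL2 and METRNL (0.147). The CCND1 and ISL2 calls also ended without Untreated 3 (0.129 and 0.0893), Wnt3a 1 (0.155 and 0.141), Wnt3a 2 (0.113 and 0.0827) or Wnt3a 3 (0.105 and 0.0562), and that of METRNL without Untreated 2 (0.156) or 3 (0.137), Wnt3a 2 (0.156) or 3 (0.191), Wnt5a 1 (0.0628) or combination 2 (0.0592) or 3 (0.0621). The NF-kB list call ended without Untreated 1 (0.0606), Untreated 3 (0.0637), Wnt3a 1 (0.11) or Wnt5a 1 (0.0596), that of the stress list without Untreated 3 (0.0528) and that of the mitosis list without Untreated 1 (0.0606).

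The second comparison asked what Wnt5a alone did. Cells given Wnt5a had less of several transcripts that cells raise under amino acid shortage or unfolded protein load. DDIT4, an inhibitor of mTORC1, fell by 1.14 ± 0.08 in log2 (SE, n = 3 per group; adjusted p = 2.26e-05), and the glutathione-degrading enzyme CHAC1 by 1.06 ± 0.12 (adjusted p = 0.000356). Cyclin D1 (CCND1) fell by 1.06 ± 0.13 (adjusted p = 0.000435). HAVCR2, which encodes the immune receptor TIM-3, rose (adjusted p = 1.27e-05); it was detected on 1 of 3 untreated arrays, and its fitted log2 value of 1.85 ± 0.13 was 0.56 in the authors' table. ID3, a target of BMP signalling, rose by 1.05 ± 0.08 (adjusted p = 2.78e-05).

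The netrin receptor gene UNC5B and the embryonic globin gene HBZ were detected on 0 of 3 untreated arrays and 3 of 3 Wnt5a arrays, at least 1.81-fold and 1.92-fold higher; CCDC46 was at least 1.47-fold higher. HIP1R (1.46), the chemokine gene CCL4L1 (1.39), PTH2 (1.37), AGPAT4 (1.37), the vasohibin gene VASH1 (1.34) and the oxysterol receptor gene GPR183 (1.26) also rose; in the authors' table HIP1R was at 0.77, CCL4L1 at 0.42, PTH2 at 0.73 and GPR183 at 0.53. CCL4L1 has near-identical paralogs, so its probe does not tell them apart. Falls were those of ETV5 (-0.99), MT1X (-0.91), MYEOV (-0.91), C3orf52 (-0.89), ADM2 (-0.89), TRIB3 (-0.89), ATF3 (-0.83), hexokinase 2 (HK2, -0.79), CEBPB (-0.74), the survival gene BCL2 (-0.72) and the serine synthesis gene PSAT1 (-0.70). The insulin receptor substrate IRS1 was at least 1.53-fold lower. In total 410 probes were higher and 327 lower, 23 and 3 of them by at least 2-fold.

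Of the 28 tested unfolded protein and amino acid stress genes, 11 fell, 0 rose and 17 did not pass with Wnt5a (14 fell when adjusted over the list alone). The fallen members included DDIT3 (-0.71), XBP1 (-0.69), SESN2 (-0.67) and asparagine synthetase (ASNS, -0.35). The list's median was -0.17 (camera adjusted p = 2.03e-12; adjusted p = 0.0591 with an estimated correlation). Ribosome biogenesis and MYC targets had a median of -0.22 (adjusted p = 6.2e-09; adjusted p = 0.00522 with an estimated correlation); 7 of 28 fell, among them NOLC1 (-0.47) and NOP16 (-0.45), and 16 when adjusted over the list alone. Hypoxia and glycolysis genes had a median of -0.07 (adjusted p = 0.00531; adjusted p = 0.0663 with an estimated correlation), where 6 of 27 fell, among them HK2 and VEGFA (-0.58), and NDRG1 rose; adjusted over the list alone 7 fell and 1 rose. TGF-beta and BMP targets had a median of 0.17 (adjusted p = 0.00944; adjusted p = 0.0727 with an estimated correlation). Of these 15 genes 4 rose: ID3, SMAD6 (0.56), TGFBI (0.30) and SMAD7, the last detected on no untreated array; adjusted over the list alone 5 rose and 1 fell.

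Immediate early and ERK feedback genes had a median of -0.15 with Wnt5a (adjusted p = 0.0149; adjusted p = 0.293 with an estimated correlation). Of 33 members 8 fell, including ETV5, ATF3, SPRED2 (-0.79) and DUSP6 (-0.76), and DUSP2 rose (0.40); adjusted over the list alone 12 fell and 4 rose. SPRY1 fell by 0.35, and 1 of its 3 probes did not pass. The p53 and apoptosis list had a median of -0.12 (adjusted p = 0.0183; adjusted p = 0.119 with an estimated correlation). The 3 of its 20 members that fell were BCL2, BCL2L1 (-0.39) and BIK (-0.40), the first pair inhibitors of apoptosis and the last an activator of it; adjusted over the list alone 4 fell and 1 rose. Canonical Wnt target genes had a median of -0.04 (adjusted p = 0.0449; adjusted p = 0.147 with an estimated correlation). CCND1, VEGFA, MYC (-0.45) and CCND2 (-0.27) fell, ABCB1 rose (0.36), and 15 of 20 did not pass; adjusted over the list alone 6 fell and 2 rose.

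All 737 probes had the same sign on both chips. In the order given, the medians of the 7 lists were -0.17, -0.21, -0.07, 0.28, -0.14, -0.10 and -0.10 on chip 1, and -0.27, -0.18, -0.14, 0.09, -0.11, -0.03 and -0.07 on chip 2. The count was 394 without Untreated 1, 464 without Untreated 2, 465 without Wnt5a 2 and 368 without Wnt5a 3. The canonical target call ended without Untreated 2 (adjusted p = 0.0578), Untreated 3 (0.0718), Wnt3a 1 (0.0538), Wnt5a 3 (0.103) or the first array of the combination (0.0513) and with a replicate block (0.0515), that of the ERK feedback list without Wnt5a 3 (0.0566), that of the p53 list without Untreated 2 (0.101), and the fall of GP1BA, given further on, without Untreated 1 (0.0593).

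The third comparison asked what both ligands together did. Cells given both ligands had less DDIT4 and CCND1 and more NKD1 than untreated cells. DDIT4 fell by 1.39 ± 0.10 in log2 (SE, n = 3 per group; adjusted p = 1.6e-05), CCND1 by 1.31 ± 0.15 (adjusted p = 0.000325) and CHAC1 by 1.27 ± 0.14 (adjusted p = 0.000322). NKD1 was at least 1.52-fold higher (adjusted p = 0.000121). PTH2 rose by 2.32 ± 0.09 (adjusted p = 1.04e-07) and HAVCR2 by 1.98 ± 0.14 (adjusted p = 1.81e-05).

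HIP1R (1.53), an expressed-sequence cluster without a gene name (1.43), the neuronal calcium sensor NCALD (1.37), LRRC75A (1.31), AGPAT4 (1.31) and GPR183 (1.30) rose with both ligands, UNC5B was at least 1.68-fold higher and CCDC46 at least 1.42-fold. ETV5 (-1.12), MT1X (-1.07), TRIM71 (adjusted p = 0.000925), ATF3 (adjusted p = 9.73e-05), TRIB3 (-0.97), MYEOV (-0.96), ADM2 (-0.93), SESN2 (adjusted p = 0.00021), CEBPB (-0.83) and HERPUD1 (-0.69) fell. So did GFI1B (-0.85), a repressor needed for megakaryocyte and erythroid development, and the interleukin gene IL1B (-0.84). In total 625 probes were higher and 467 lower, 28 and 6 of them by at least 2-fold.

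With both ligands 11 of 28 stress genes fell and 0 rose (13 when adjusted over the list alone), with a median of -0.20 (camera adjusted p = 1.69e-10; adjusted p = 0.0904 with an estimated correlation). Of 28 ribosome biogenesis and MYC targets 8 fell, such as NOLC1 (-0.55) and WDR43 (-0.52), and 12 when adjusted over the list alone; the median was -0.27 (adjusted p = 6.28e-08; adjusted p = 0.00767 with an estimated correlation). Immediate early and ERK feedback genes had a median of -0.19 (adjusted p = 0.000906; adjusted p = 0.192 with an estimated correlation), with 8 of 33 lower, SPRY1 higher (0.54), and 12 lower and 2 higher when adjusted over the list alone. The proplatelet cytoskeleton list had a median of -0.10 (adjusted p = 0.00441; adjusted p = 0.157 with an estimated correlation). Its 4 fallen members of 40, also 4 when adjusted over the list alone, were VASP (-0.56), TPM4 (-0.50), VCL (-0.37) and DIAPH1 (-0.26), which bind or assemble actin filaments. Hypoxia and glycolysis genes had a median of -0.02 and a mean of -0.13 (adjusted p = 0.012; adjusted p = 0.115 with an estimated correlation), with 5 of 27 lower and 1 higher (6 and 1 when adjusted over the list alone). TGF-beta and BMP targets had a median of 0.22 (adjusted p = 0.0497; adjusted p = 0.157 with an estimated correlation). Of 15 members 5 rose, including ID3 (0.75) and BMPR2 (0.70), and ID1 fell (-0.45), as they did when adjusted over the list alone.

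All 1092 probes had the same sign on chip 2, the only chip with both groups (1 untreated array), where the medians of the 6 lists, in the order given, were -0.23, -0.26, -0.18, -0.10, -0.10 and 0.10. The higher share was 57.2% and became 66.9% of 753 under median scaling. The count was 238 without Untreated 1, 717 without Wnt3a 1 and 655 without array 3 of the combination. The TGF-beta call ended with a replicate block (adjusted p = 0.0597), without background correction (0.0558), with all probes of a gene averaged (0.0578) and without any 1 of Untreated 2 or 3, Wnt5a 1, 2 or 3, or combination 1 or 2 (0.0545 to 0.103).

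**Figure D2:**
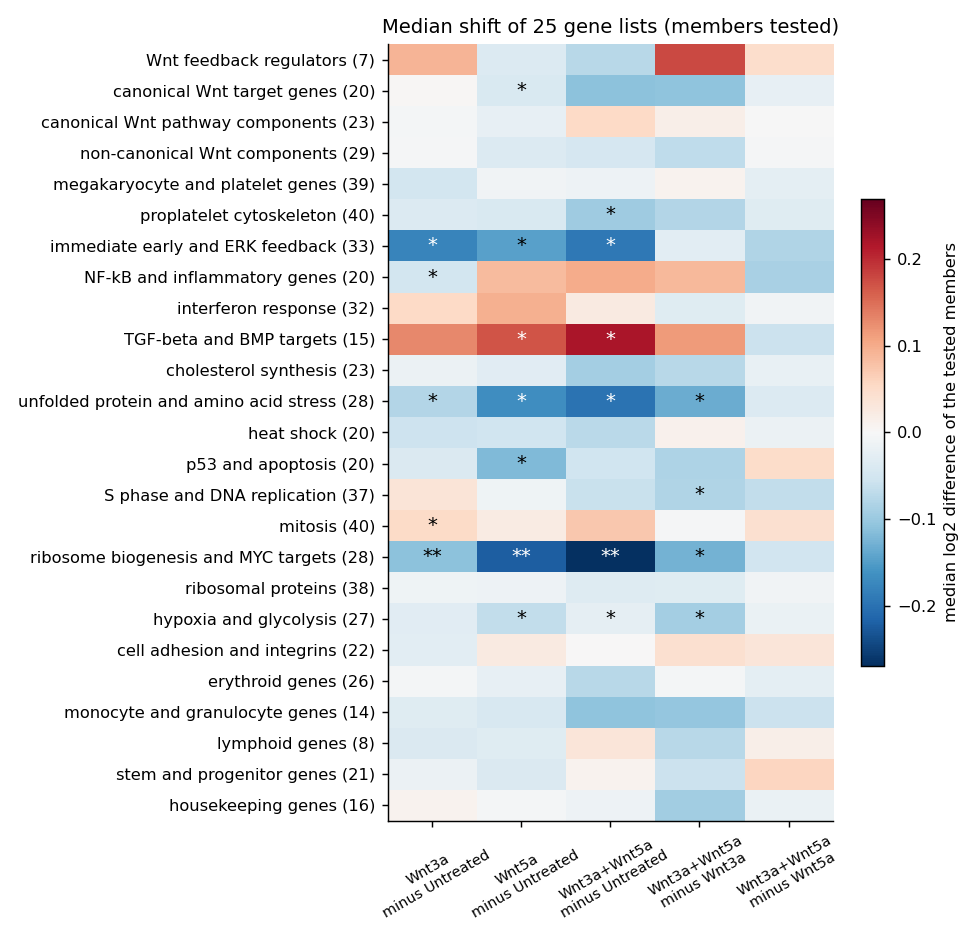
Median log2 difference of the tested members of 25 gene lists in 5 comparisons (colour); 1 star marks a camera adjusted p below 0.05 and a double star one that also held with an estimated correlation. Ribosome biogenesis and MYC targets carry a double star in the 3 comparisons with untreated cells, at -0.11, -0.22 and -0.27.

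Adding Wnt5a to Wnt3a lowered EPAS1, KCTD12 and ADM, which Wnt3a alone raised. EPAS1 fell by 0.87 ± 0.07 in log2 (SE, n = 3 per group; adjusted p = 6.51e-05), KCTD12 by 0.88 ± 0.14 (adjusted p = 0.00546), and ADM by 0.82 ± 0.09 (adjusted p = 0.000562). The TCF/LEF factor LEF1, which did not pass with Wnt3a alone, fell by 0.48 ± 0.09 (adjusted p = 0.00971). DDIT4 fell by 0.97 ± 0.10 (adjusted p = 0.00031), with IRS1 (-0.95), TRIM71 (adjusted p = 0.00573), CHAC1 (-0.77), CASS4 (adjusted p = 0.00562), QKI (adjusted p = 0.0211), SLC3A2 (-0.71), CCND1 (-0.69), CEBPB (-0.67), HERPUD1 (-0.61), MYC (-0.29) and a further expressed-sequence cluster (at least 1.28-fold lower). HAVCR2 (1.87), VASH1 (1.57), CCL4L1 (1.38), AGPAT4 (1.34), CCL4L2 (1.33), HIP1R (1.32), RGS2 (1.32), SMAD6 (0.87), ID3 (0.82), CCL2 (0.71) and the Wnt co-receptor LRP5 (0.64) rose, and HBZ, UNC5B and CCDC46 were at least 1.82-fold, 1.75-fold and 1.48-fold higher. The other tested probes of MYC, LRP5, SLC3A2 and QKI did not pass.

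In this comparison 12 of 28 stress genes fell and 0 rose, as when adjusted over the list alone, with a median of -0.13 (camera adjusted p = 8.37e-08; adjusted p = 0.141 with an estimated correlation). Ribosome biogenesis and MYC targets had a median of -0.13 (adjusted p = 0.00461; adjusted p = 0.128 with an estimated correlation), where ODC1 and JTV1 were the 2 of 28 that fell (4 fell and 1 rose when adjusted over the list alone). S phase and DNA replication genes had a median of -0.08 (adjusted p = 0.00534; adjusted p = 0.247 with an estimated correlation), with RRM2 (-0.44) the 1 of 37 that fell, also when adjusted over the list alone. Hypoxia and glycolysis genes had a median of -0.09 (adjusted p = 0.0234; adjusted p = 0.141 with an estimated correlation), with 4 of 27 lower and 1 higher, or 7 and 1 when adjusted over the list alone. On chip 2 (1 Wnt3a array) all 648 probes had the same sign and the medians of these lists were -0.17, -0.15, -0.09 and -0.14. The count was 86 without Wnt3a 1, 422 without Wnt3a 2 and 333 without array 3 of the combination, and the hypoxia call ended without array 1 of the combination (adjusted p = 0.0811). Without Wnt3a 1 the calls of LEF1 (adjusted p = 0.124), CCND1 (0.167), CHAC1 (0.187), QKI (0.208), IRS1 (0.0897), TRIM71 (0.0753), CASS4 (0.0708), the sequence cluster (0.124) and MYC (0.317) ended; those of QKI and MYC also ended without other arrays (up to 0.0953).

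Adding Wnt3a to Wnt5a raised 17 probes of 15 genes. LRRC75A rose by 1.17 ± 0.14 in log2 (SE, n = 3 per group; adjusted p = 0.00361), EPAS1 by 1.08 ± 0.07 (adjusted p = 2.49e-05), PTH2 by 0.95 ± 0.09 (adjusted p = 0.00104) and SPRY1 by 0.89 ± 0.10 (adjusted p = 0.00228). MMD (0.90), CEMIP2 (0.86), MAP1B (0.81), STXBP6 (0.78) and TMEM158 (0.77) also rose, and NKD1 was at least 1.62-fold higher (adjusted p = 0.00262). Of the 17 probes, 15 were also higher with Wnt3a alone. By limma 0 probes fell, while 1243 probes had an unadjusted p under 0.05 in either direction. Among the decreases with the smallest p were NDUFC2 (at least 1.12-fold lower, adjusted p = 0.0537), TAL1 (-0.41, adjusted p = 0.107), IL1B (-0.39, adjusted p = 0.111) and CEACAM1 (at least 1.17-fold lower, adjusted p = 0.162). Of the 25 lists 0 passed by camera at either correlation or by fry, while 4 passed with all probes of a gene averaged, 3 without background correction, 1 without the chip term, 2 without combination 1 and 1 without Wnt5a 3. All 17 had the same sign on chip 2 (1 Wnt5a array), the count was 11 without Wnt5a 2, and the call of STXBP6, of which the other probe did not pass, ended without any of 11 of the 12 arrays (up to 0.124).

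**Figure D3:**
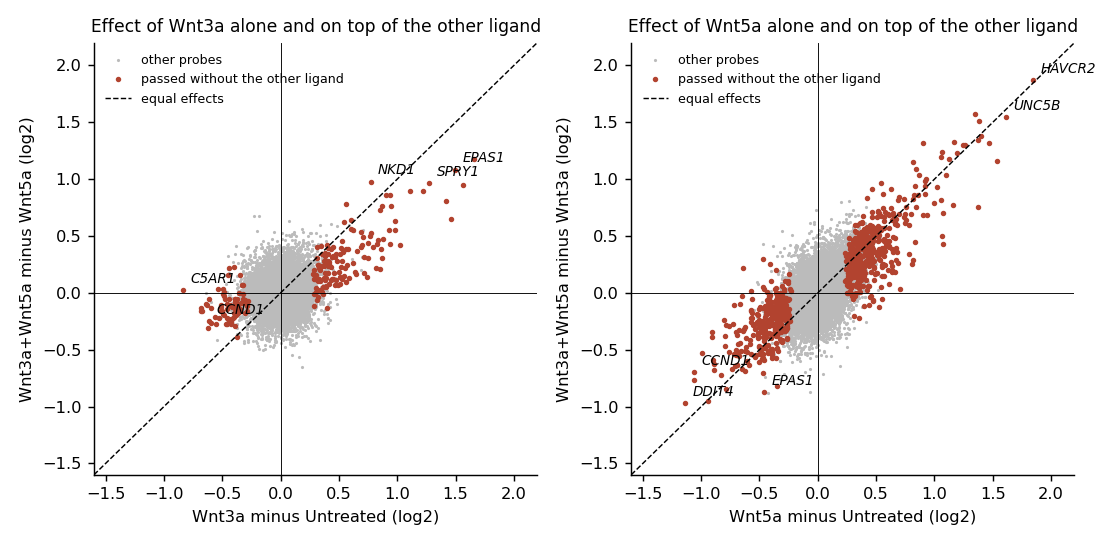
Log2 effect of Wnt3a (left) and of Wnt5a (right), without the other ligand on the x axis and on top of it on the y axis; each point is a probe and the dashed line marks equal effects. Probes that passed without the other ligand are coloured; MAP1B lies at 1.42 and 0.81 for Wnt3a, and HAVCR2 at 1.85 and 1.87 for Wnt5a.

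Whether the ligands' effects added up was tested by the interaction. By limma 0 probes passed, with 1099 at an unadjusted p under 0.05 and a smallest adjusted p of 0.262; the count was 1 without background correction, 1 in the authors' table and 3 with a trended and robust variance. Among the largest values with the smallest p were those of C5AR1 (0.86 ± 0.14), FAM89A (0.63), BCL2 (0.61), OSTM1 (0.56) and MAP3K12 (0.56), and of NCALD (-0.64 ± 0.11), ZNF311 (-0.63), MYCN (-0.60) and GSTO2 (-0.58), all at an adjusted p of 0.262 (SE, n = 3 per group). S phase and DNA replication genes had a median interaction of -0.07 (camera adjusted p = 0.0419; adjusted p = 0.81 with an estimated correlation), with 0 of 37 past the threshold over all probes or adjusted over the list alone. That call ended by fry (adjusted p = 0.213), without the chip term (0.144) and without Untreated 1 (0.0794) or 2 (0.105), Wnt3a 1 (0.0905), Wnt5a 2 (0.492) or combination 2 (0.122) or 3 (0.055).

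Averaged over both backgrounds, Wnt3a changed 246 probes (176 higher, 70 lower) and Wnt5a 1729 (945 higher, 784 lower). Among the rises on average with Wnt3a were LRRC75A (1.42), EPAS1 (1.29), PTH2 (1.26), MAP1B (1.12) and MMD (1.06), and among the falls SLC30A1 (-0.47), CCND1 (-0.43), MT1X (-0.42), DUSP5 (-0.41) and IRX3 (-0.41). Among the rises with Wnt5a were HAVCR2 (1.86), UNC5B, VASH1 (1.46), CCDC46 and HIP1R (1.39), and among the falls DDIT4 (-1.05), IRS1, CHAC1 (-0.91), CCND1 (-0.88) and TRIM71; UNC5B and CCDC46 were detected on 0 arrays without Wnt5a and IRS1 on 0 arrays with Wnt5a alone. The higher share for Wnt3a was 71.5%; under median scaling 194 of 218 probes were higher. Its count was 75 without Untreated 1, 56.5% of the full count without Wnt3a 2, 134 without Wnt3a 3 and 154 without Wnt5a 2; that of Wnt5a was 952 without Untreated 1, 868 without Wnt3a 1 and 1044 without Wnt5a 3, and that of the F test 651, 771 and 739. Without Untreated 1 the average Wnt3a calls of CCND1 (adjusted p = 0.228), DUSP5 (0.161), MT1X (0.156) and IRX3 (0.0531) ended, and those of the first 3 also ended without other arrays (up to 0.153).

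Set against each other at their different doses, the ligands differed in 829 probes, 363 higher and 466 lower with Wnt3a. EPAS1 was higher with Wnt3a by 1.96 ± 0.06 in log2 (SE, n = 3 per group; adjusted p = 4.37e-09), SPRY1 by 1.46 ± 0.09 (adjusted p = 1.8e-06) and LEF1 by 0.50 ± 0.07 (adjusted p = 0.00164). KCTD12 (1.52), LRRC75A (1.52), CEMIP2 (1.37), DCUN1D3 (1.27), TMEM158 (1.27), MAP1B (1.11), MMD (1.08), ADM (0.92), the Wnt-induced receptor TNFRSF19 (0.89) and HHEX (0.73) were also higher with Wnt3a, as were NKD1 and IRS1 by at least 1.36-fold and 2.01-fold. HAVCR2 (-1.73), VASH1 (-1.66), CCL4L1 (-1.47), AGPAT4 (-1.40), GRK5 (-1.33), CCL4L2 (-1.29), HIP1R (-1.26), ID3 (-1.12), SMAD6 (-0.88), CCL2 (-0.85), NFATC1 (-0.76) and LRP5 (-0.67) were lower with Wnt3a. UNC5B, HBZ and CCDC46 were lower by at least 1.89-fold, 2.00-fold and 1.53-fold.

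Stress genes were higher with Wnt3a than with Wnt5a, 12 of 28 with 0 lower (14 and 0 when adjusted over the list alone; median 0.14, camera adjusted p = 1.6e-07; adjusted p = 0.0988 with an estimated correlation). NF-kB and inflammatory genes were lower with Wnt3a, 6 of 20 (8 when adjusted over the list alone; median -0.12, adjusted p = 0.00126; adjusted p = 0.0988 with an estimated correlation), among them CCL3 (-0.95), CCL2, NFKBIA (-0.58) and BIRC3 (-0.51). The p53 and apoptosis list was higher (median 0.09, adjusted p = 0.00984, or 0.0988 with an estimated correlation; 4 of 20 higher and 1 lower, 5 and 2 when adjusted over the list alone), as were ribosome biogenesis and MYC targets (0.08, adjusted p = 0.00984, or 0.0988 with an estimated correlation; 0 of 28 either way). Canonical Wnt targets (median 0.10, adjusted p = 0.0405; adjusted p = 0.128 with an estimated correlation) had 3 of 20 higher, LEF1, MYCN and SOX4, and 2 lower (8 and 2 when adjusted over the list alone). Hypoxia and glycolysis genes (median 0.04, adjusted p = 0.0404; adjusted p = 0.124 with an estimated correlation) had 5 of 27 higher and 1 lower (6 and 1 when adjusted over the list alone). All 829 probes had the same sign on both chips, and the medians of the 6 lists, in the order given, were 0.17, -0.11, 0.14, 0.11, 0.09 and 0.04 on chip 1 and 0.21, -0.20, 0.10, 0.07, 0.17 and 0.07 on chip 2. The higher share was 43.8% and became 60.1% of 667 under median scaling. The count was 437, 513 and 535 without Wnt3a 1, 2 or 3 and 502 and 422 without Wnt5a 2 or 3; the canonical target call ended without Wnt3a 1 (adjusted p = 0.0753), Wnt3a 3 (0.051) or Wnt5a 3 (0.139), and the hypoxia call without Wnt3a 1 (0.0597), Wnt3a 2 (0.0839) or Wnt5a 2 (0.0909).

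Each ligand moved some genes the opposite way. EPAS1 rose 2.82-fold with Wnt3a, fell by 0.46 in log2 with Wnt5a and rose by 0.62 with both. SPRY1, CEMIP2, TMEM158, ADM, the homeobox gene DLX1 and BHLHE40 were likewise higher with Wnt3a and lower with Wnt5a. CCL2, SMAD6, PLEC and CXXC5 were lower with Wnt3a and higher with Wnt5a. Such opposite calls covered 18 probes of 17 genes, where independent lists would share 5.43. Of these probes 12 were higher with Wnt3a and 6 higher with Wnt5a. Calls in the same direction were above independent lists too, with 23 higher (3.88 for independent lists) and 44 lower (1.86). Both comparisons use the untreated arrays, so the lists are not independent.

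Calls in the same direction were 23 higher and 44 lower for Wnt3a and Wnt5a, 76 and 52 for Wnt3a and the combination, and 282 and 225 for Wnt5a and the combination, each against untreated cells. Because these comparisons share the untreated arrays, their fold changes across probes were set against simulations without any effect. The correlation was 0.34 for Wnt3a and Wnt5a (0.50 in simulations), 0.43 for Wnt3a and the combination (0.43) and 0.76 for Wnt5a and the combination (0.43). The covariances of the same pairs were 0.00820, 0.0127 and 0.0277, each above the highest of the simulations (0.00468, 0.00477 and 0.00474). All simulations in this paragraph drew the noise of each probe separately and do not cover variation shared by many probes on an array. Such variation on the untreated arrays was not excluded as a source of the higher covariances. The effects of a ligand alone and on top of the other compare separate groups, joined only by the chip term and the spread fitted to all arrays. Those of Wnt5a correlated at 0.57 and shared 310 calls with 0 opposite. Those of Wnt3a correlated at 0.23 with 15 shared calls (simulated correlations at most 0.0234 and 0.0275). Probes are not independent replicates. The correlation of 0.76 was 0.563 without Wnt5a 2. The 67 calls that Wnt3a and Wnt5a shared in the same direction were 23 without Untreated 1, 41 and 42 without Untreated 2 or 3, 31, 28 and 33 without Wnt3a 1, 2 or 3 and 44 without Wnt5a 3; the 76 and 52 of Wnt3a and the combination became 38 without Untreated 1, 83 without Untreated 3 and 63, 63 and 73 without Wnt3a 1, 2 or 3; and the 282 and 225 became 173 without Untreated 1, 311 without Wnt5a 2 and 277 without Wnt5a 3. The 310 shared calls were 78 without Wnt3a 1, 205 without Wnt5a 2, 171 without Wnt5a 3 and 198 without array 3 of the combination.

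Several markers of Wnt signalling and of the megakaryocyte lineage were not detected or did not pass. AXIN2, TCF7, SP5, RNF43 and the platelet factor gene PF4 were detected on 0 arrays. CTNNB1, ZNRF3, ITGA2B, ITGB3, GP9, GATA1 and NFE2 did not pass in any comparison of 2 groups. Against untreated cells ITGA2B, the integrin alpha subunit of platelets, was at 0.01 ± 0.08 with Wnt3a, -0.14 ± 0.08 with Wnt5a and -0.19 ± 0.09 with both (SE, n = 3 per group). The von Willebrand factor receptor subunit GP1BA fell with Wnt5a (-0.35 ± 0.06, adjusted p = 0.00797) and with both (-0.43 ± 0.07, adjusted p = 0.00511), and was at -0.20 with Wnt3a (adjusted p = 0.213); without Untreated 1 the first pair had an adjusted p of 0.0593 and 0.113. LEF1 was at 0.26 with Wnt3a (adjusted p = 0.147), -0.25 with Wnt5a (adjusted p = 0.0854) and -0.23 with both (adjusted p = 0.138), and it fell in the average effect of Wnt5a (-0.36, adjusted p = 0.00148). NKD1 passed as higher in that same average, at 0.06 to 0.39 in log2 over the alternatives, but the call was kept in only 10 of 24 of them. MYC fell with Wnt5a (-0.45) and both (-0.51) and was at -0.22 with Wnt3a (adjusted p = 0.119).

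**Figure D4:**
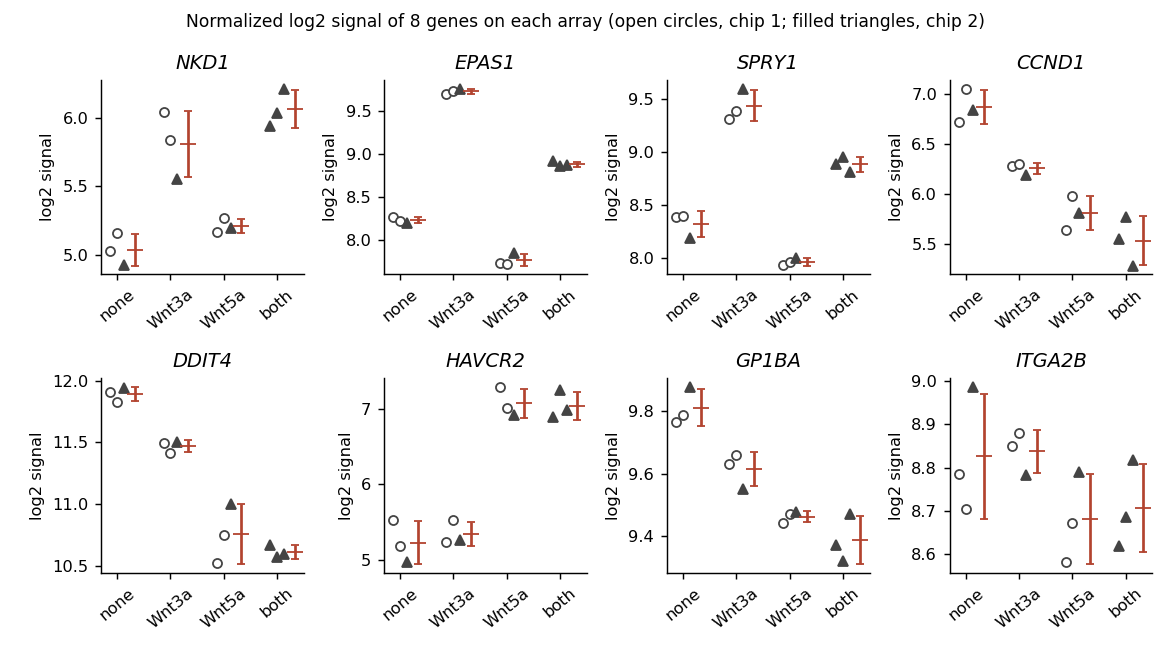
Normalized log2 signal of 8 genes on each array (open circles, chip 1; filled triangles, chip 2) in untreated cells (none) and with Wnt3a, Wnt5a or both; the bar beside each group is the mean ± SD of its 3 arrays. EPAS1 was higher with Wnt3a and lower with Wnt5a than in untreated cells, and DDIT4 was lower with each ligand.

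The 14 lists without a call in any comparison of 2 groups had the following smallest camera adjusted p over the 6 comparisons. For lists on Wnt signalling it was 0.145 for Wnt feedback regulators (7 tested), 0.695 for canonical Wnt pathway components (23) and 0.383 for non-canonical Wnt components (29). For lineage lists it was 0.0845 for megakaryocyte and platelet genes (39), 0.695 for erythroid genes (26), 0.107 for monocyte and granulocyte genes (14), 0.251 for lymphoid genes (8) and 0.0748 for stem and progenitor genes (21). It was 0.0554 for interferon response (32), 0.138 for cholesterol synthesis (23), 0.0696 for heat shock (20), 0.362 for ribosomal proteins (38), 0.61 for cell adhesion and integrins (22) and 0.255 for housekeeping genes (16). Of the 39 megakaryocyte and platelet genes, 3 fell and 0 rose with Wnt3a (GATA2, THBS1 and TBXA2R), 2 fell with Wnt5a (GFI1B and GP1BA) and 6 fell with both, in each case with 0 higher; adjusted over the list alone 7 fell and 2 rose, 2 fell, and 7 fell.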

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

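No test in this part was chosen after its result was seen. S phase and DNA replication genes were singled out because their response to Wnt3a differed with and without Wnt5a by a test of the difference itself: the list's median interaction was -0.07 (camera adjusted p = 0.0419, 37 genes). It was the only one of 25 lists to pass for the interaction by camera in the fit as reported; 1 list passed by fry and 3 without the chip term, this list not among them, and 2 with a replicate block, without Wnt3a 2 or without Wnt5a 1. The adjusted p was 0.81 with an estimated correlation, 0.213 by fry and 0.144 without the chip term, and it was 0.0794 without Untreated 1, 0.105 without Untreated 2, 0.0905 without Wnt3a 1, 0.492 without Wnt5a 2, 0.122 without combination 2 and 0.055 without combination 3. No biological explanation was tested.

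For the interaction over single probes the real count was 0, which all 100 regroupings of the 12 arrays reach by construction, so they say nothing about chance there. The highest other count was 241, in 1 regrouping, which points to a structure of the arrays. It set 5 arrays with Wnt5a and 1 without against the others, as did other regroupings with a count of 0 or 1, so what raised it was not settled.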

How the results depend on the processing

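All alternatives were planned. Of 149 calls of named genes 0 turned direction, 108 of 149 did not pass on chip 2 alone, where groups of 1 array were assumed to vary like the combination, 10 of 56 on chip 1 alone, 18 of 124 with the 2 groups alone, 14 without Untreated 1, 14 without Wnt3a 1, 11 without the filter and 3 under median scaling. Signal over background limits what can be seen: 14051 of 48803 probes were tested, and values near background are compressed. The combination stood on 1 chip and the groups held 3 arrays, so the test for outlying arrays was not applied. Fold sizes also moved, 91 of 149 called log2 values of named genes to over 1.5 times smaller in the submitters' value table (median ratio 0.591) and 55 with no background correction (0.807): over the alternatives the log2 value ranged from 0.56 to 1.96 for HAVCR2, -1.17 to -0.35 for CCND1 and -1.18 to -0.32 for CHAC1 with Wnt5a, and from 0.51 to 2.13 for LRRC75A with Wnt3a. The share of probes higher with Wnt3a than with Wnt5a turned from 43.8% to 60.1% under median scaling, and the median of the NF-kB list with Wnt3a from -0.05 to 0.01. The counts below moved by over 1.5 times, and the cause was not tested except where a stricter threshold, more probes or fewer arrays give it by construction.

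Counts follow for Wnt3a minus Untreated (213), Wnt5a minus Untreated (737), combination minus Untreated (1092), combination minus Wnt3a (648), combination minus Wnt5a (17), Wnt3a minus Wnt5a (829), interaction (0), average Wnt3a (246), average Wnt5a (1729) and F test (1236). With no background correction, Wnt3a minus Untreated gave 341, combination minus Wnt3a 1060, combination minus Wnt5a 28 and the interaction 1. With median scaling, combination minus Wnt3a gave 371. In the submitters' value table, Wnt3a minus Untreated gave 346, combination minus Wnt3a 991 and the interaction 1. With no filter, the counts were 119, 456, 520 and 269 for the first 4, 515 for Wnt3a minus Wnt5a, 133 and 1068 for the averages and 735 for the F test. With a detection p under 0.05 on 3 arrays, they were 131 for Wnt3a and 618 for the combination minus Untreated, 343 for combination minus Wnt3a and 147 for average Wnt3a. Combination minus Wnt3a was 397 with no chip term and 413 with the chip as random block.

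On chip 1 alone, Wnt3a and Wnt5a minus Untreated gave 45 and 247 and Wnt3a minus Wnt5a 313. On chip 2 alone, the first 6 gave 3, 0, 61, 9, 0 and 11, the averages 10 and 143 and the F test 23. With 2 groups alone and the chip term, Wnt5a and the combination minus Untreated gave 477 and 224, combination minus Wnt3a 184, combination minus Wnt5a 2 and Wnt3a minus Wnt5a 540. With trend and robust, Wnt3a minus Untreated gave 359, combination minus Wnt3a 1115, combination minus Wnt5a 36 and the interaction 3. With array weights (0.527 for Wnt5a 1 to 3.34 for Wnt5a 3), Wnt5a and the combination minus Untreated gave 1379 and 1856, Wnt3a minus Wnt5a 1846, the averages 419 and 3196 and the F test 2565. With BH over 6 comparisons together, combination minus Wnt5a gave 100. At an adjusted p of 0.10, the first 4 gave 350, 1157, 1727 and 1334, Wnt3a minus Wnt5a 1257, average Wnt3a 394 and the F test 1905. At 1.5-fold, the first 4 gave 57, 140, 224 and 135, Wnt3a minus Wnt5a 170, the averages 37 and 111 and the F test 281.

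Without each array in turn, the counts ranged from 76 to 229, 368 to 759, 238 to 1317, 86 to 882, 11 to 18 and 422 to 886 for the first 6, 0 to 0 for the interaction, 75 to 216 and 868 to 1974 for the averages and 651 to 1285 for the F test. List calls over 6 comparisons (28) were 3 with an estimated correlation, 50 with fry and 24 to 30 without each array in turn.

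Shared calls were 103 for Wnt3a and Wnt5a minus Untreated (67), 481 for Wnt5a alone and on top of Wnt3a (310) and 26 for Wnt3a alone and on top of Wnt5a (15) with no background correction. Without each array in turn they were 23 to 74, 78 to 399 and 11 to 16, and 38 to 144 for Wnt3a and the combination minus Untreated (76 higher and 52 lower) and 173 to 582 for Wnt5a and the combination minus Untreated (507); the correlation of the last pair was 0.563 to 0.796, against 0.759.

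The arrays of a number were not shown to pair: 11 of 18 same-number pairs correlated above 0.1 and the lowest was -0.16, although 9 of 12 arrays were closest to their own number (6 after chip adjustment). With a replicate block and the chip term, the first 6 counts were 218, 886, 918, 555, 18 and 1011, and with the block but no chip term 207, 712, 1073, 555, 22 and 793.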

Other observations

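The tests that chose their question after the result was seen were the removal of the chip term for Wnt3a added to Wnt5a, the stress list's value with Wnt3a, and, for the metal genes, the list itself and its tests for cross-hybridization and for the untreated arrays. Of the 26 erythroid genes 3 rose with Wnt5a, 1 fell and 22 did not pass, and the list did not pass (camera adjusted p = 0.919). ALAS2 (0.39), which encodes the first enzyme of haem synthesis, rose, HBZ was detected only with Wnt5a, and the fetal globin gene HBG2 fell (-0.31). Of 21 stem and progenitor genes 0 rose and 2 fell with Wnt5a, LMO2 (-0.48) and HHEX (-0.48), and 19 did not pass (list adjusted p = 0.0748); with Wnt3a 1 rose (MECOM, 0.69), 2 fell (GATA2 and ID1) and 18 did not pass (list adjusted p = 0.815). Of 14 monocyte and granulocyte genes 3 fell with both ligands, CSF1R (-0.62), FCGR1A (-0.62) and CD33 (-0.27), 1 rose (CEBPA, detected on no untreated array) and 10 did not pass (list adjusted p = 0.107).

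Of 20 NF-kB and inflammatory genes 6 rose with Wnt5a, 2 fell and 12 did not pass. BIRC3 (0.47), CCL2 (0.46), CD83 (0.40), NFKBIA (0.38) and RELB (0.32) rose, and CCL3 was detected on no untreated array and on all 3 arrays with Wnt5a. IL1B (-0.45) and BCL3 (-0.35) fell, and the list as a whole did not pass (camera adjusted p = 0.0858). Of 29 non-canonical Wnt components 1 rose with Wnt5a (NFATC1, 0.65), 3 fell, WNT5A itself (-0.44) among them, and 25 did not pass (list adjusted p = 0.383).

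Fewer probes passed for Wnt3a added to Wnt5a (17) than for Wnt3a alone (213). Each count had its own Benjamini-Hochberg cutoff, so the gap between the counts does not measure a difference in response. At an unadjusted p under 0.05 the counts were 1243 and 1706. With adjustment over the pairwise comparisons together, 100 probes passed for Wnt3a added to Wnt5a. How much of the gap came from the separate cutoffs was not tested. The larger standard error of the combination (1.15 times) was argued against as the whole account. Without the chip term 23 probes passed, against 167 for Wnt3a alone, again with separate cutoffs. Selection of large values was argued against only for noise that is independent between probes. Over the 246 probes chosen by the average Wnt3a effect the median interaction, turned to the sign of that effect, was -0.123. The 100 simulations without interaction gave -0.02 to 0.03, but they drew the noise of each probe separately. They do not cover variation shared by many probes on an array. The hypothesis that Wnt5a lowers the response to Wnt3a predicted a negative median without any array, and the highest was -0.117. That median kept the 246 probes chosen on all arrays, so a change of sign was unlikely from the start. Of these probes 75.6% lay against the sign, and the median was -0.0707 in the authors' table. The hypothesis was found and tested on the same data, and 0 single probes passed for the interaction. Variation shared between probes was not excluded as the source of the negative median.

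Of 28 amino acid and unfolded protein stress genes 11 fell with Wnt5a and 17 did not pass (list adjusted p = 2.03e-12; adjusted p = 0.0591 with an estimated correlation). Both groups had 2 arrays on chip 1 and 1 on chip 2, so an offset between the chips cancels in their difference by design. The medians were -0.170 on chip 1 and -0.268 on chip 2, where 2.5% of random lists lay below -0.05 and -0.07. These medians add no separate support. They come from the arrays that gave the list call, and the random lists do not keep the correlation between genes of this list. The normalization was argued against by a median of -0.156 where it lay nearest 0 among the alternatives (-0.167 as reported). A shared property of the added protein solutions cannot be told apart from the ligands for the part of the change that Wnt3a also gave (median -0.0791), because the series has no vehicle group; the further difference between the ligands passed (adjusted p = 1.6e-07; adjusted p = 0.0988 with an estimated correlation), but their protein amounts differed as well.

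Metallothionein genes and the zinc exporter gene SLC30A1, which zinc induces through MTF1, were lower with each ligand. The medians of these 6 genes, which were grouped after their values were seen, were -0.47 with Wnt3a, -0.42 with Wnt5a and -0.60 with both. Of 7 probes 6 passed in all 3 comparisons, and that of MT1H did not pass with Wnt3a (-0.42, adjusted p = 0.0683). Cross-hybridization between metallothionein transcripts cannot account for the fall of SLC30A1, which is no metallothionein (highest adjusted p 0.0140). Whether the metallothionein probes read one another's transcripts cannot be told from SLC30A1 and stays open. Without each array in turn, the median nearest 0 in the 3 comparisons with untreated cells was -0.359. The genes had been grouped by their values on all arrays, so a large move toward 0 was unlikely from the start. Dependence on 1 array was therefore not settled. Higher values of the shared untreated arrays alone cannot be told apart from an effect of the ligands. In comparisons without the untreated group the medians were -0.0975 (combination minus Wnt3a) and -0.154 (combination minus Wnt5a). Only the latter lay below 2.5% of random lists (-0.138 and -0.0907). The untreated arrays still entered both medians through the chip term. No biological explanation was tested.

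For comparisons of 3 arrays with 3 there were 10 splits, too few for a share under 0.05. The real count and the highest other were 213 and 0 for Wnt3a, 737 and 0 for Wnt5a, 1092 and 0 for both ligands, 648 and 1 for the combination minus Wnt3a, 17 and 1 for the combination minus Wnt5a, and 829 and 0 for Wnt3a minus Wnt5a; in each, 1 split, the real one, gave as many. For lists called, they were 5 and 4, 7 and 3, 6 and 5, 4 and 2, 0 and 2, and 6 and 2, with 1 split as large in each but the fifth, where a count of 0 makes all 10 as large. The mixed splits with 4 lists for Wnt3a and 5 for both ligands had 0 probes called. A list call by camera at the preset correlation is therefore not by itself evidence of a treatment effect. Among 100 regroupings of the 12 arrays, only the real one gave as many probes for the average effect of Wnt3a (246, highest other 192), of Wnt5a (1729, highest other 1) and for the F test (1236, highest other 2). A share of 1 in 100 is the smallest that could be reached. It argues against chance as the source of any difference among the groups but does not exclude it. The average effect of Wnt3a was not tested by itself, because regrouping also mixed arrays with and without Wnt5a. The regrouping with 192 set 5 arrays with Wnt5a and 1 without against the others, as did other regroupings with a count of 0, so what raised it was not settled.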
